A study of Escherichia coli with 9 samples.

How the data were processed

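RecA ChIP-seq and input libraries of Escherichia coli K-12 MG1655 derivatives were analysed from the deposited processed files, 1 file per library and 9 libraries in 9 groups. Cells were grown at 37 °C in minimal medium with glucose and casamino acids, crosslinked for 10 min with 1% formaldehyde and precipitated with an anti-RecA antibody at 1 in 100, per the labels' protocols. The deposited files give, for each base of the strain's own reference sequence, the coverage (hits), the substitutions and the deletions, with strands merged. They were made with pyPileup from Novoalign alignments, per the file headers, and Novoalign was version 2.07, per the submitters' processing notes. The signal used here is the deposited coverage per base, which is not normalised and whose thresholds are all 0, per the file headers. How reads with several matches were placed is not recorded. The genome build is not given in the sources used here, so positions are those of the palindrome strain's deposited sequence, and array strain positions were carried over through exact matches of 31 bp.

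The coverage of the library without the palindrome was displaced against its own base column. It lagged by 0 bp up to 359455, by 661 bp from 359456 to 365393 and by 900 bp from 365394 on. In 20 windows after lac its median lag was 900 bp, and in the other libraries lags ran from -1 to 3 bp. Its substitution rates by reference base spread over 0.00985 points as deposited and 0.163 points after moving, against 0.171 in the palindrome strain. The coverage was moved back for the values reported, a choice made after seeing the data, and the positions as deposited are an alternative. The second change point, a step of 239 bp, is not exact. After moving, this library had a relative signal of 1.63 inside the 246 bp palindrome, which its strain lacks. Its values in lacZ next to the palindrome are therefore approximate.

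No genome annotation comes with the files. Genes were placed by matching open reading frame lengths and the spacing of neighbours to a RefSeq gene table (ASM584v2). The table's coordinates were starting points and were shifted by local offsets that these matches set. RNA genes took the offset shared by the protein genes on both sides. Of 4290 protein genes 4267 were placed, 4260 of them by length and spacing, with 213 RNA genes. Peptide matches for recA, lexA, dnaA, lacI, lacY and rpoB fell at the start of the placed frame in 6 of 6, and 7 of 7 ribosomal small-subunit RNA starts fell in a placed gene. Some genes of the lists have no value. The gene ttcA was not placed, and neither were the genes listed with it from ynaJ on, among them fnr. Whether that stretch is absent from the sequence is not established here. The names gidA, xisD, exoD, renD and nmpC are not among the protein genes of the table.

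Coverage was averaged in 1 kb bins and divided by the median of bins more than 200 kb from lacZ. The lacY side starts at the lacZ end of lacY (363062) and runs toward the origin, and the mhpA side starts at the start of mhpA (368749) and runs away from it. Excess is relative signal minus that of the library without the palindrome in the same bin, given as a mean per bin over 100 kb and over 20 kb. The near share is the part of the 100 kb excess that lies within 20 kb. Counting intervals at 95% come from 1000 Poisson redraws of the number of reads, coverage divided by the mean aligned length, or from exact Poisson ratios. Some bins have no value. These are 1 bin on the lacY side in the library without the palindrome, where moving its coverage back leaves a gap, and 2 bins in prpE without matching sequence in the array strains.

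Each 100 kb excess was set against 41 other windows. The planned SD of near shares over such windows was replaced by central 68% ranges, since windows with ribosomal RNA operons make shares of small sums very large. Trends over the 6 array strains used exact two-sided permutation of all orders for Pearson's r and Spearman's rho, with Benjamini-Hochberg adjustment over 3 relations and a refit without the 2 strains farthest from the median number of sites. The chance per χ site was fitted by least squares on a grid of 0.005. The terminus window was 100 kb centred on dif, set against other windows of that size. Asymmetry at χ used 5 kb flanks and 10000 sets of random positions with random strand, and 2000 sets in the alternatives. Gene list medians were compared with 10000 random lists of the same size matched on mean signal. No paired analysis was possible because each group has 1 library. No p-value is given across genes or bins.

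The named genes are every gene of the lac region list. For the natural χ strain over the library without the palindrome and over its input they are also the 10 highest and 10 lowest genes of at least 300 bp with a relative signal of at least 0.25 in the denominator, more than 200 kb from lacZ and 1 per 5 kb. For each other list they are its 2 highest and 2 lowest members. Bins are named by the gene they overlap most; dosP and ydeA at the terminus were named in this way. The gene recA over the library without the palindrome and the genes relE, relB and mhpR in single array strains were singled out after their values were seen. The lists, comparisons, tests, rule for named genes and the settings given as chosen beforehand were fixed before the data were examined.

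Depth ran from 1019924 to 5430295 mapped reads, and 0.397% of bases had no read in the shallowest library. Between the 8 ChIP libraries, the correlation of far bins ran from 0.856 to 0.987. The trend, fit, gene list and χ asymmetry statistics were tested on simulated data. For the recognition fit over 6 strains a chance per site of 0.3 was recovered as 0.31 and 0.6 as 0.585. These simulated ratios followed the fitted curve, with the same near share in every strain. Their recovery checks the fitting only, and not whether the curve holds. For the ratio trend the largest log2 errors were 0.06 and 0.05, and for the near share 1.22 and 1.05 points, each over 6 strains. For the gene groups, on 3775 genes, log2 changes of 0.58 and 1 were recovered as 0.56 and 0.98, and 3.5% of unchanged lists fell outside the central 95%. For the asymmetry at 917 χ sites, simulated on a flat background with every site raised, a median of 0.14 was recovered as 0.16.

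Settings chosen beforehand for comparison were scaling by the whole total, background from the strain's own flanks or from the input, 5 kb bins, 50 kb windows, a near part of 10 kb, each array strain left out in turn, the natural χ strain added, terminus windows of 50 and 200 kb, χ flanks of 2 and 10 kb, division by input, and a minimum input signal. Settings added after seeing the data were the positions as deposited, a near part of 14 kb, bins shared by every library, the first 1, 2 or 3 kb left out with either background, a terminus window of 400 kb, signal beside over between the terminus χ sites, χ sites more than 400 kb from dif, random strands matched to the replichore, the terminus list without uxaC, a member that lies far from dif, random lists matched on distance from dif, and the prophage list without members within 200 or 400 kb of dif. The substitution counts were left out of the comparisons and the deletion counts were not used. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.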

Results

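RecA binding to the chromosome was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in growing Escherichia coli K-12 MG1655 derivatives. RecA is the recombinase that coats single-stranded DNA during the repair of double-strand breaks. In most of the strains a 246 bp interrupted palindrome in lacZ, the β-galactosidase gene, serves as the place where the replicating chromosome is broken. The RecBCD enzyme then degrades both ends until it meets χ, the sequence GCTGGTGG read in 1 orientation, and loads RecA beyond it. Each strain carries a χ array at the lacZ and lacY boundary, on the origin-proximal side of the palindrome, and an array of 3 χ sites in mhpA on the origin-distal side. There were 9 libraries, 1 per group. They were RecA ChIP from a strain without the palindrome, RecA ChIP and input DNA from a strain with the palindrome and its natural χ sites, and RecA ChIP from 6 palindrome strains that lack natural χ sites in codB, prpE, mhpC and cynX and carry 1 to 6 χ sites in the lacZ array. Per the labels all the ChIP strains share lacIq, lacZχ- and rph+. The natural χ sites kept in the natural χ strain therefore do not include one in lacZ. There are no biological replicates, so no difference between strains has a replicate check.

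Mapped reads numbered 1019924 in the strain without the palindrome, 1399936 in the natural χ strain and 5430295 in its input. In the strains with 1, 2, 3, 4, 5 and 6 χ sites they numbered 1418612, 1756525, 3112953, 2706745, 2155672 and 1029583. A median 1 kb bin held between 186 reads (no palindrome) and 1120 reads (input). Relative signal below is coverage divided by the median 1 kb bin lying more than 200 kb from lacZ in the same library, so 1 is the level of a typical bin. Intervals in parentheses are 95% intervals and cover counting error only, since duplicate molecules and differences between cultures are not seen in them. Positions refer to the sequence of the palindrome strain, 4626827 bp long, as the files give it; the genome build is not given in the sources used here. The palindrome lies at 366184 to 366429, the lacZ array of 3 sites at 363085 to 363128 and the mhpA array at 369457 to 369500, about 3.06 and 3.03 kb from the palindrome.

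The pair of libraries with and without the palindrome addresses where RecA binds when lacZ is broken. With the palindrome, RecA signal was high over the genes on both sides of lacZ, beginning beyond each χ array. Over the first 20 kb on the lacY side, which runs toward the origin, mean relative signal was 6.27 with the palindrome and 1.01 without it. On the mhpA side it was 3.08 and 0.917. The lactose permease gene lacY (361809 to 363062) was at 9.50 with the palindrome against 1.02 without, a log2 ratio of 3.22 (3.03 to 3.42), and the galactoside acetyltransferase gene lacA (361132 to 361743) was at 10.3 against 0.884, a log2 ratio of 3.55 (3.25 to 3.85). In mhpD, an enzyme gene of aromatic acid degradation, the levels were 6.02 and 0.911, a log2 ratio of 2.73 (2.47 to 2.99).

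The other genes of the lac region outside the arrays were also higher with the palindrome, without a strict order by distance. The cyanate genes cynS, cynR, cynX and cynT had log2 ratios of 3.43, 3.34, 3.25 and 2.99, and the cytosine deaminase gene codA had 2.80. Per the labels cynX carries a GmR insertion, and its placed length of 1815 bp includes it. Farther toward the origin, codB, the cytosine permease gene, was at 1.98 and the propionate catabolism genes prpE, prpC, prpD and prpB were at 2.66, 2.53, 2.34 and 2.11. On the other side mhpC, mhpF, mhpT, mhpB and mhpE lay between 2.17 and 2.65. The gene mhpA, which holds its array inside it, had 1.18 (0.99 to 1.37). Between the arrays the signal stayed near the typical bin, with mean relative signal 1.24 with the palindrome and 1.19 without. There lacZ had a log2 ratio of 0.28 (0.14 to 0.43), the regulator gene mhpR had -0.17 (-0.47 to 0.13) and the lac repressor gene lacI had -0.22 (-0.43 to -0.01). The directions of lacZ and lacI depended on the placement of the no-palindrome coverage; with its positions as deposited they were -0.06 and 0.14.

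Signal fell off with distance. On the lacY side relative signal with the palindrome was 9.51 from 0 to 2 kb, 9.68 from 2 to 5 kb, 7.81 from 5 to 10 kb, 3.82 from 10 to 20 kb, 1.97 from 20 to 50 kb and 1.23 from 50 to 100 kb. The highest bins of that strain were in cynX (359063 to 360062) at 10.6 and in mhpD (371749 to 372748) at 6.17. The cynX bin lies mostly in the gap of the moved coverage without the palindrome, so it has no value in that library. Over 100 kb the ratio of the library with the palindrome to that without was 2.63 (2.59 to 2.67) on the lacY side and 1.52 (1.50 to 1.55) on the mhpA side. On the lacY side the sum with the palindrome includes the cynX bin and the sum without it does not. The value of 2.63 is therefore too high, and its interval does not cover this. The 20 kb mean on that side likewise includes this bin only with the palindrome. The mean excess per bin, over bins with a value in both libraries, was 1.43 on the lacY side and 0.533 on the mhpA side. Among 41 other windows of 100 kb it had a mean of -0.0756, an SD of 0.204 and a highest value of 0.481, so both sides lay above every other window, and 7.38 and 2.98 SDs above the mean of those windows. This compares 2 libraries and not replicated conditions. In the array strains the lacY side also lay above every other window. Their mhpA side was only 1.22 to 2.38 SDs above the mean of their windows. On that side 2 other windows were as high in the strains with 1, 2, 4 and 6 sites.

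**Figure D1:**
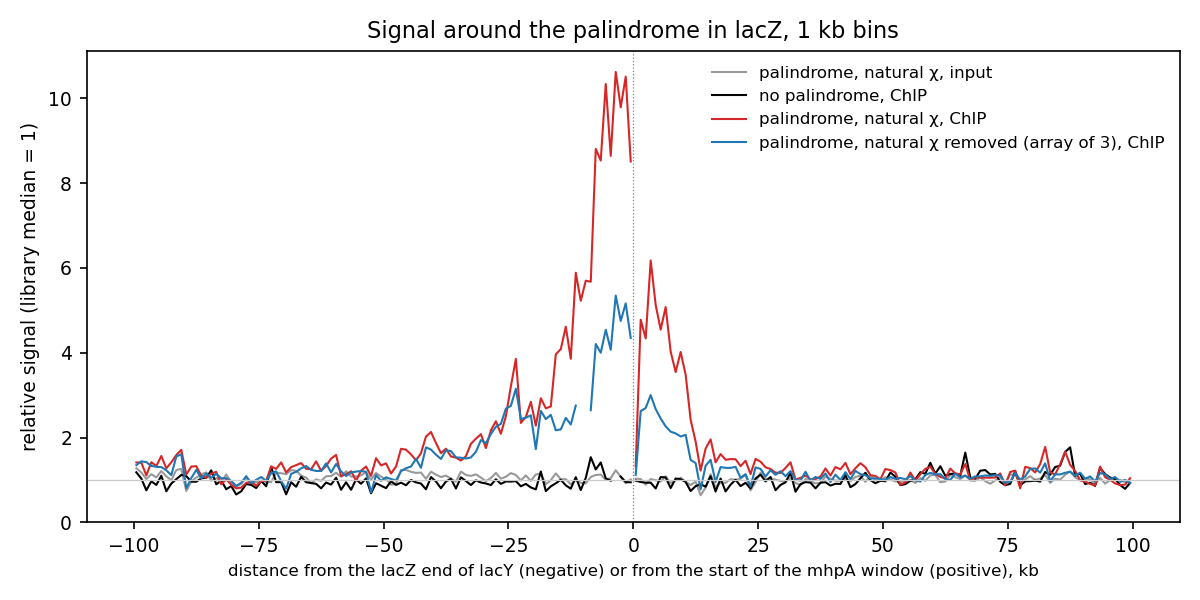
Relative signal (library median 1, vertical axis) against distance in kb from the lacZ end of lacY (negative) or from the start of mhpA (positive) in 1 kb bins, with lines for the input, the ChIP library without the palindrome, the natural χ ChIP library and the array strain with 3 sites; breaks in a line are bins without a value. In the natural χ strain the highest bin reaches 10.6 on the lacY side and 6.17 on the mhpA side.

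Dividing the natural χ ChIP library by its own input addresses the same question with copy number and mappability removed. Over the first 20 kb the ratio was 6.06 on the lacY side, log2 2.60 (2.57 to 2.62), and 3.23 on the mhpA side, log2 1.69 (1.66 to 1.72). The genes lacA, cynR, lacY and cynT had log2 ratios of 3.48, 3.31, 3.24 and 3.20, while lacZ had 0.32 (0.22 to 0.42) and mhpR 0.14 (-0.08 to 0.36). All 22 genes of the lac region list were above 0. Over 100 kb the log2 ratios were 1.20 (1.19 to 1.22) and 0.63 (0.62 to 0.65).

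Away from lacZ the highest genes over input were ribosomal RNA genes, whose reads cannot be assigned to a single copy of the 7 operons: rrlE at 2.69, rrsD at 2.68, rrsC at 2.66, rrlB at 2.63, rrlG at 2.62 and rrlA at 2.61. They were followed by ydeA (2.00), an arabinose exporter gene near the replication terminus, secG (1.95), a protein translocase gene, csrB (1.81), a regulatory RNA, and ddpB (1.74), a dipeptide transport gene near the terminus. The lowest were waaS (-0.88), a lipopolysaccharide gene, ygeG (-0.85), ymfD (-0.76), elaB (-0.76), appY (-0.70), gadE (-0.65), an acid resistance activator gene, yeeN (-0.65), yfdI (-0.61), ydhX (-0.60) and dcuR (-0.59). Of 4226 bins more than 200 kb from lacZ, 120 had a log2 ratio above 1 and 0 were below -1, around a median of -0.07 with an SD of 0.38. Within 100 kb, 29 of 100 bins on the lacY side and 12 of 100 on the mhpA side were above 1. Scaling by whole totals instead of the median bin shifts every log2 ratio over input by -0.148.

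The natural χ strain and the array strain with 3 sites carry the same arrays and differ, per the labels, in natural χ sites. The pair addresses whether those sites shape the spread of RecA. The array strain's sequence is also shorter, at 4625423 against 4626827 bp, with no match over part of prpE. Distances follow the natural χ strain's sequence, where the prpB χ site lies at 14.9 kb, against 13.5 kb on the array strain's own. This works toward a larger mean distance and a smaller near share in the array strain, by an amount not measured. On the lacY side the active natural χ sites within 20 kb of the array go from 6 to 1 and the nearest moves from 2.23 to 13.5 kb. On that side RecA signal lay farther from the break without them. The share of the 100 kb excess that fell within 20 kb was 67.5% in the natural χ strain and 50.2% in the array strain, a difference of -17.2 points (-18.3 to -16.1), and the mean distance of the excess was 19.7 and 25.8 kb, a difference of 6.03 kb (5.34 to 6.71). That distance difference was 2.35 kb with each strain's own flanks as background, 3.40 kb with the input as background and 3.62 kb with 50 kb windows. The level is no measure of natural χ sites here. The gene lacY was at 9.50 in the natural χ strain and 4.63 in the array strain with 3 sites, but at 17.8 and 13.6 in those with 2 and 6 sites, which lack the same natural χ sites. The rise beside the terminus χ sites in the library with 3 sites was also lower, 57.4% of that in the natural χ strain.

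On the mhpA side, where the single natural χ site within 100 kb, 1.91 kb from the array, is absent from the array strains, the near share was 81.3% and 83.4%, a difference of 2.09 points (-2.19 to 7.02) that was not detectable at this depth. It was negative under 5 other settings, at -16.5 points with whole-total scaling, -3.33 to -4.25 with own flanks, input or 50 kb windows and -0.378 with a near part of 10 kb. The mean distance differed by -3.05 kb (-6.36 to -0.269), and the first 4 of these settings gave a positive difference instead. Adding the excess of the other windows as noise gave central 68% ranges of 67.2 to 72.6% for the natural χ strain and 47.8 to 58.7% for the array strain on the lacY side, which do not overlap. Bins in prpE have no value in the array strains, and with only the bins shared by every library the lacY-side difference was -15.0 points. The file headers date the coverage files of the 2 strains to different months, so processing batch and natural χ sites cannot be told apart.

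Across the 6 array strains the number of χ sites next to lacY is the only labelled difference, which addresses how often a single χ site is recognised. RecA signal near the lacY array, relative to that near the unchanged mhpA array, rose with the number of sites. The ratio of the 20 kb excess on the lacY side to that on the mhpA side was 2.25 (2.17 to 2.33) with 1 site, 2.42 (2.37 to 2.47) with 2, 2.44 (2.33 to 2.56) with 3, 2.56 (2.44 to 2.69) with 4, 2.63 (2.52 to 2.74) with 5 and 2.65 (2.55 to 2.74) with 6. The slope was 0.0779 per site. With the excess of other windows added as noise, central 68% ranges of the ratio overlapped, at 2.19 to 2.53 with 1 site and 2.43 to 2.98 with 6, so the counting intervals understate the uncertainty of each point. In the natural χ strain, with 3 sites, the ratio was 2.32 (2.25 to 2.39). The absolute level followed no such order, since lacY was lowest with 3 sites at 4.63 and highest with 2 sites at 17.8, and mhpD was at 5.01, 7.11, 2.91, 2.68, 3.38 and 5.04 in strains with 1 to 6 sites.

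The lacY-side signal also became more concentrated near the array. Its near share was 45.7, 47.1, 50.2, 50.3, 56.0 and 55.0% in strains with 1 to 6 sites, a slope of 2.08 points per site. On the mhpA side, whose array is the same in these strains, the near share was 77.3, 67.7, 83.4, 83.4, 85.3 and 79.1%, a slope of 1.78 points per site.

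Each relation was tested over 6 strains with exact two-sided permutation of all 720 orders, and p was adjusted over the 3 relations. For the ratio Pearson's r was 0.967 (exact p 0.00278, adjusted 0.00833) and Spearman's rho was 1 (exact p 0.00278, adjusted 0.00833), the smallest p that 6 strains allow. For the lacY-side near share r was 0.951 (exact p 0.00833, adjusted 0.0125) and rho 0.943 (exact p 0.0167, adjusted 0.025). For the mhpA-side near share r was 0.514 (exact p 0.308, adjusted 0.308) and rho 0.6 (exact p 0.242, adjusted 0.242). Without the strains with 1 and 6 sites r was 0.973, 0.933 and 0.830, each with exact p 0.0833, the smallest that 4 strains allow. Whether the lacY-side slope differs from the mhpA-side slope was not tested. With each strain's own flanks as background, r for the ratio was 0.797 (exact p 0.0722) and for the lacY-side near share 0.781 (exact p 0.0722); with the input library as background r for that share was 0.811 (exact p 0.0583). Adding the natural χ strain as another strain with 3 sites ended the relation of the near share, with r 0.385 (exact p 0.401). The file headers place all 6 array strains in the same month. Even so, the library with 3 sites had 48.9 mean aligned bases per read, against 46.7 to 46.8 in the other array strains. Across 10 kb bins far from lacZ and dif, which are not replicates, the libraries of the strains with 3 to 6 sites correlated with each other at 0.952 to 0.987 and with the other 4 ChIP libraries at 0.856 to 0.972. Within the 4 strains with 3 to 6 sites r was 0.950 for the ratio (exact p 0.0833), 0.848 for the lacY-side share (exact p 0.25) and -0.539 for the mhpA-side share (exact p 0.5), and the strains with 1 and 2 sites are too few for a value.

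**Figure D2:**
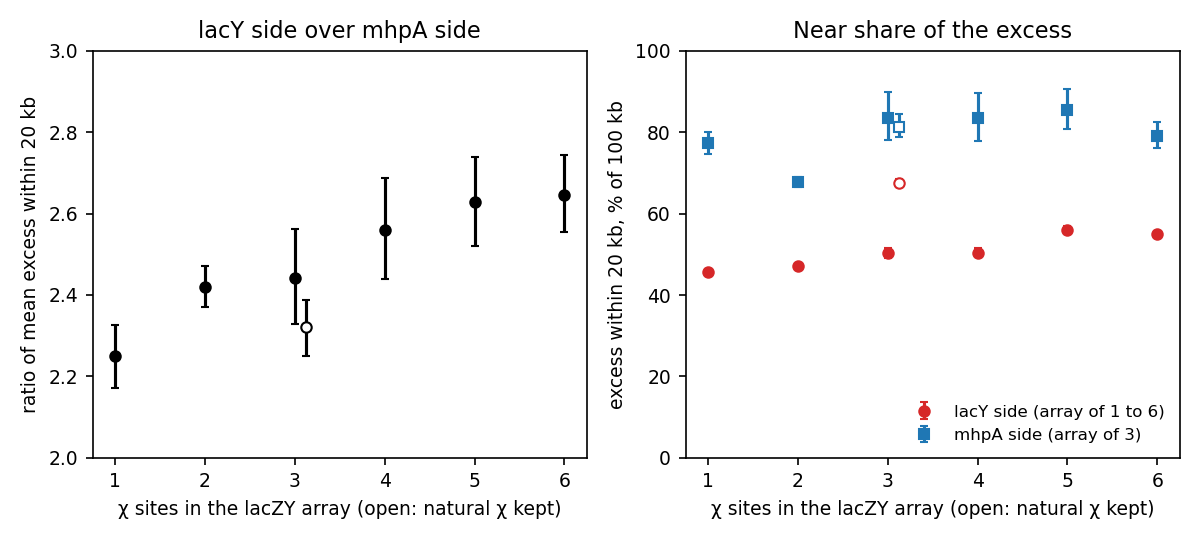
Left, ratio of the mean RecA excess within 20 kb on the lacY side to that on the mhpA side, and right, the share in percent of the 100 kb excess that lies within 20 kb on each side, both against the number of χ sites in the lacZ array. Points are single libraries, bars are 95% counting intervals (hidden by the point where short), and open points are the natural χ strain; in the array strains the ratio runs from 2.25 to 2.65.

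A curve in which RecBCD recognises each χ site in the lacZ array with an equal and independent chance gave 0.87 (0.83 to 0.905) per site. The plateau of the lacY to mhpA ratio was 2.55 (2.48 to 2.64), and the curve accounted for 69.6% of the variance of the ratio over the 6 strains, against 93.6% for a straight line, so the ratios do not follow the curve closely. Near parts of 10 and 14 kb gave 0.785 and 0.77 per site, below that interval; the next active χ site lies at 13.5 kb. Leaving out the strain with 1 site gave 0.705 and leaving out the strain with 5 gave 0.88, the lowest and highest of such refits. The equal chance is an assumption of the curve. Another is that the lacY-side excess vanishes without array sites, which no strain here tests. The ratio was already 2.25 with 1 site, so the chance per site rests on that assumption.

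The terminus, where replication forks meet, was compared in the same way as lacZ. RecA signal there was higher in every palindrome ChIP library than in the library without the palindrome. In the 100 kb centred on dif (1575926 to 1575953), the site where sister chromosomes are resolved, the natural χ strain was 1.82 (1.78 to 1.86) times the library without the palindrome. The strains with 1 to 6 χ sites were at 2.05, 3.59, 1.34, 1.50, 1.45 and 2.19 times. In each of these 7 libraries the dif window ranked 1 among 40 windows of that size. Over input, the natural χ strain was at 1.69 and the library without the palindrome at 0.927, where it ranked 38.

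The terminus signal lay in 2 flanks with a lower middle. In the natural χ strain relative signal was 1.93 over the 20 kb left of the plus-strand χ site at 1553878, 2.10 over the 20 kb right of the minus-strand χ site at 1595220, and 0.820 over the 41.3 kb between them. The library without the palindrome had 0.841, 0.989 and 0.616 in the same places. A ter site, where replication forks are halted, lies at 1594337 to 1594352, beside the right-hand χ site. In 2 kb bins the right-hand rise cannot be placed at one of these sites rather than the other. The highest bins of the natural χ strain were in dosP, a cyclic dinucleotide phosphodiesterase gene, at 2.77 on the left and in ydeA at 3.16 on the right. The 10 genes highest over the library without the palindrome, outside the lac region, all lay within 186 kb of dif. They were ydfV with a log2 ratio of 1.64 (1.18 to 2.12), the peroxidase gene osmC at 1.52 (1.14 to 1.93), yneK at 1.48, the diguanylate cyclase gene dosC at 1.48, ycjY at 1.45, ydeI at 1.43, the acid shock gene asr at 1.39, the antitoxin gene hicB at 1.31, ydfR at 1.27 and ydfI at 1.18. Of 210 windows of 20 kb, 9 of the 10 highest lay within 100 kb of dif and 10 within 200 kb.

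**Figure D3:**
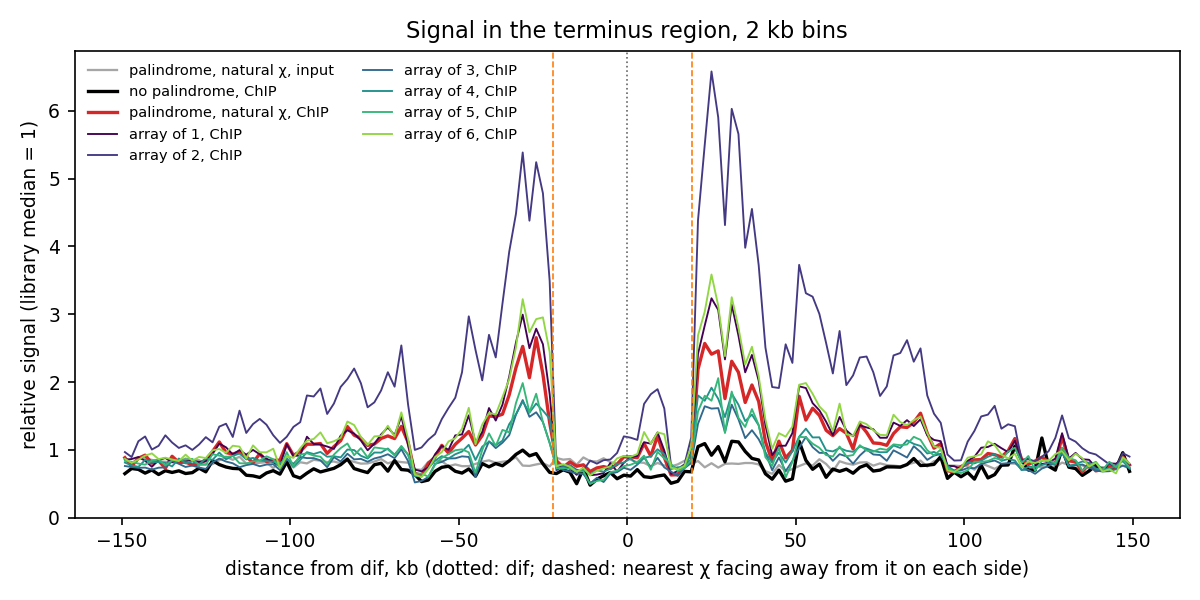
Relative signal (library median 1, vertical axis) against distance in kb from dif in 2 kb bins, with a line for each of the 9 libraries, a dotted line at dif and dashed lines at the nearest χ site on each side that faces away from dif. In the natural χ strain relative signal is 1.93 and 2.10 in the 20 kb outside the χ sites and 0.820 between them.

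In the 7 palindrome ChIP libraries the excess beside these terminus χ sites was 19.8 to 42.1% of the 20 kb excess on the lacY side. Both excesses carry the scaling and the precipitation yield of their library, which alone would make them vary together, so their relation across libraries was not used.

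χ sites elsewhere address whether RecA loading at χ is visible without an engineered break. At 917 of the 1010 GCTGGTGG sites, those more than 200 kb from lacZ, signal over 5 kb on the side where RecA would be loaded was compared with 5 kb on the other side. The median log2 ratio was -0.01 in the library without the palindrome and -0.01 in the natural χ strain, at percentiles 13.8 and 19.5 of 10000 sets of random positions. It was 0.01 (percentile 97.9) in the strain with 2 sites and 0.02 (percentile 98.0) in the strain with 5, which were the 2 of 9 libraries outside the central 95%. With 10 kb flanks 0 libraries were outside, and with signal divided by input 3 were, those of the strains with 4, 5 and 6 sites. With 2 kb flanks 2 were outside in opposite directions, the strain with 2 sites (percentile 98.0) and the natural χ strain (percentile 1.40). A median of 0.14 at these 917 sites, simulated on a flat background with counting noise only, was recovered as 0.16. Real coverage is not flat, so this does not show how small an asymmetry could be seen here.

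Gene lists written before the data were examined were compared between the natural χ strain and the strain without the palindrome. Terminus genes were higher with the palindrome, as were the cryptic prophage genes near dif, and ribosomal RNA and ribosomal protein genes were lower. All 20 genes of the terminus list had a log2 ratio above 0, with a median of 0.59 (percentile 100 of 10000 random lists matched on mean signal). The list holds uxaC, which lies at 3228503 to 3229915, 1653 kb from dif; the other 19 genes lie within 100 kb of dif and had a median of 0.61 (percentile 100). Among them the multiple antibiotic resistance genes marB and marR had 1.20 (0.63 to 1.80) and 1.20 (0.74 to 1.67), while the fumarase gene fumA had 0.10 (-0.17 to 0.37); the distant uxaC had 0.03 (-0.20 to 0.25). Of 28 prophage genes 24 were above 0, with a median of 0.55 (percentile 100), or percentile 99.6 of random lists matched on distance from dif instead. The 19 members within 200 kb of dif had a median of 0.66, percentile 95.4 with matching on distance, and the 9 farther members had 0.13 (percentile 88.9, or 94.7 with matching on distance). Matched on distance, the whole list lay outside the central 95% and neither part did, so place near dif and membership of a prophage are not separated. The highest were dicC at 1.37 (0.72 to 2.08) and dicB at 1.36 (0.55 to 2.25), from the Qin prophage in the terminus region, and the lowest were xisE at -0.27 (-0.93 to 0.38) and intA at -0.23 (-0.49 to 0.03). The toxin and antitoxin genes relE and relB had 1.19 and 1.18.

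All 14 ribosomal RNA genes had a lower relative signal with the palindrome, with a median log2 ratio of -0.72 (percentile 0.05). Their median relative signal was 10.8 without the palindrome, 6.55 in the natural χ strain and 1.07 in the input. It was 4.85, 3.84, 2.53, 2.15, 4.51 and 3.63 in the strains with 1 to 6 χ sites. Of 35 ribosomal protein genes 31 were below 0, with a median of -0.55 (percentile 1.50); rplM had -0.86 (-1.12 to -0.60), rpsI -0.84 (-1.12 to -0.55), rpsC 0.23 (-0.01 to 0.47) and rplP 0.16 (-0.16 to 0.48). Of 25 other highly transcribed genes 23 were below 0, with a median of -0.31 (percentile 5.03), from the cold shock protein gene cspE at -0.93 (-1.28 to -0.58) and the ATP synthase gene atpD at -0.63 to hupB at 0.03 and the glycolysis gene pgk at 0.13.

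Genes of the SOS response, the DNA damage regulon controlled by LexA, had a median of 0.12 (percentile 99.8), with 15 of 24 above 0. The toxin gene tisB had 0.79 (-0.18 to 1.85), yebG 0.60 (0.08 to 1.13), recA itself 0.48 (0.26 to 0.70), umuD -0.30 (-0.79 to 0.20) and sbmC -0.31 (-0.75 to 0.14). With the median of the 7 palindrome libraries in place of the natural χ strain the SOS median was 0.02 (percentile 93.2) and recA was at -0.01. Genes of double-strand break repair outside the SOS regulon had a median of -0.21 (percentile 3.01), with 14 of 16 below 0. The nuclease gene sbcC had 0.35 (0.20 to 0.49), sbcD 0.12 (-0.12 to 0.37), priC -0.32 (-0.74 to 0.10) and the primosome gene priB -0.60 (-0.87 to -0.33). Of 13 origin genes 12 were below 0, with a median of -0.22 (percentile 82.0), from asnA at -0.67 and atpI at -0.54 to asnC at -0.01 and mioC at 0.02. The lac region list, 20 of 22 above 0, had a median of 2.53 (percentile 100).

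Outside the lists, the 10 lowest genes among 3442 more than 200 kb from lacZ included glnQ, a glutamine transport gene, at -1.12 (-1.39 to -0.84), the cytochrome bd gene cydA at -0.93, the uracil salvage gene upp at -0.93, carA at -0.79 and cysU at -0.79. The other 5 were rplM, rrsG (-0.83), rpsM (-0.83), rrsC (-0.76) and secG (-0.76). Of the 9 lists, 6 had a median outside the central 95% of random lists. With the median of the 7 palindrome libraries 5 did, without the SOS list, and with the no-palindrome positions as deposited 4 did, without the SOS and ribosomal protein lists. With random lists matched on distance from dif 6 did, without the terminus list (percentile 91.0), whose neighbours are high too, and with the other highly transcribed genes (percentile 0.01). With the no-palindrome positions as deposited rplM, rpsM and secG changed sign, to 0.84, 0.14 and 2.15.

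Over input the same lists gave a different order. Ribosomal RNA genes had a median log2 ratio of 2.63 (percentile 100), with all 14 above 0, and the lowest was rrsB at 2.58. Ribosomal protein genes had 0.97 (percentile 94.9), with 35 of 35 above 0, from rpsT at 1.42 and rplN at 1.26 to rpsC at 0.57 and rpsB at 0.50. The other highly transcribed genes had 0.28 (percentile 87.3), with 23 of 25 above 0, led by cspA at 2.02, with dnaK and groL lowest at -0.14 each. The terminus list had 0.45 (percentile 100), with 17 of 20 above 0, or 0.54 (percentile 100), with 16 of 19 above 0, without uxaC, including the peptidase gene dcp at 1.25 and, among the lowest, fumC at -0.15. Prophage genes had 0.28 (percentile 100), with 22 of 28 above 0, including relB at 1.19 and, lowest, intA at -0.40 and ydaT at -0.33. The 9 prophage genes more than 200 kb from dif had -0.03 (percentile 77.5), and the 19 nearer ones had 0.62 (percentile 98.15 with matching on distance).

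The SOS list had a median over input of 0.08 (percentile 98.97), with 16 of 24 above 0 and recA highest at 0.86 (0.70 to 1.01). Scaled by whole totals that median was -0.07. Break repair genes outside the SOS regulon had -0.06 (percentile 33.4), with 11 of 16 below 0, priB at 0.96 and recD at -0.27. Origin genes had 0.23 (percentile 21.7), with atpI at 0.98, atpB at 0.61 and gyrB at 0.01, and 12 of 13 above 0. The lac region list had 2.47 (percentile 100). Of the 9 lists 5 were outside the central 95%, and percentiles describe these libraries only. With the no-palindrome positions as deposited, which enter the matching of random lists on mean signal, 7 were, with ribosomal proteins (percentile 98.6) and other highly transcribed genes (percentile 98.0) added. With matching on distance from dif 6 were, without the terminus (percentile 89.6) and prophage (percentile 93.8) lists and with the ribosomal protein (percentile 100), other highly transcribed (percentile 100) and origin (percentile 99.8) lists.

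**Figure D4:**
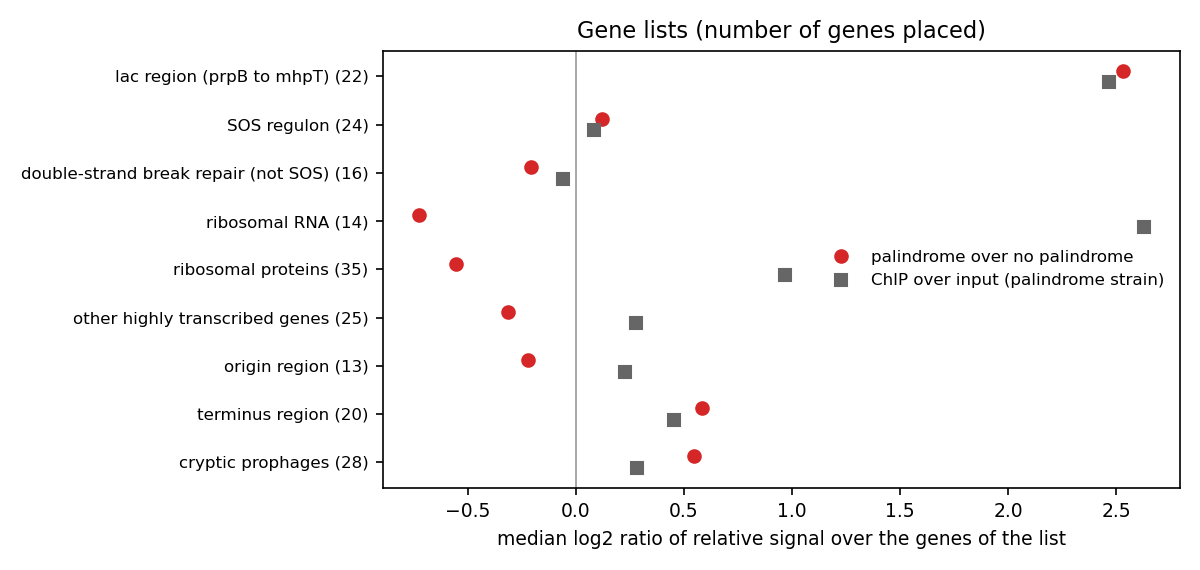
Median log2 ratio of relative signal over the genes of each list (horizontal axis), with circles for the natural χ strain over the strain without the palindrome, squares for the natural χ strain's ChIP over input, and the number of genes placed in parentheses. The lac region medians are 2.53 and 2.47, and the ribosomal RNA medians are -0.72 and 2.63.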

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

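Of the tests in this part, only the one at the terminus was chosen before its result was seen; the tests of strain variants, of reads from 1 strand and of depth were chosen afterwards.

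The substitution column of the coverage files, which no comparison above uses, carried a signal of its own beside the broken lacZ and at the terminus. In the 7 palindrome ChIP libraries reference A was substituted more often than reference T over the 20 kb on the lacY side, by a median of 0.750 percentage points (0.527 to 1.15 over libraries), with A at 2.11 to 3.13% and T at 1.55 to 1.98%. On the mhpA side the sign was opposite, with a median of -0.456 (-0.829 to -0.365). Beside the χ sites at the terminus the median was 0.540 (0.372 to 0.984) left of dif and -0.707 (-1.02 to -0.498) right of it. In 189 other windows of 20 kb the difference ran from -0.247 to 0.319 over these libraries, and each of the 7 lay outside its own windows in all 4 places. The library without the palindrome had 0.179, 0.0828, 0.157 and -0.112 in the same order and the input 0.0627, -0.0352, 0.00176 and 0.00146, all within their own windows.

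Reference C minus G differed between groups of ChIP libraries. In the natural χ strain it lay outside its own windows in all 4 places, with the signs of A minus T. It was 0.409 and -0.364 on the lacY and mhpA sides and 0.475 and -0.529 left and right of dif. Without the palindrome it lay outside its windows (-0.197 to 0.244) at the terminus, at 0.294 left and -0.288 right of dif. In the 6 array strains it ran from -0.0738 to 0.142, with 0 of 24 values outside. The file headers date the files of the natural χ and no-palindrome libraries to a different month from those of the array strains.

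Strain variants against the reference are excluded, since without positions substituted in more than 20% of reads the lacY-side median was 0.746. A difference that only rises or only falls with depth is excluded. In 7 of 7 libraries signal rose from left of dif to right of dif to the lacY side. The difference lay above, below and above every other window in that order. Whether its size follows depth, with a sign set by the side, was not tested. The strand that RecA holds may carry more damage or misreading, and the difference lay above every other window left of dif and below every other window right of dif in 7 of 7 libraries. Reads that come mostly from 1 strand, with a fixed error rate per read base, would give the same signs at the terminus, and the mean of the A and T rates on the lacY side, 1.99%, lay above all windows in 4 of 7 libraries only. The files merge strands, so these 2 explanations cannot be told apart here, and since C minus G splits the ChIP libraries as the months do, a biological origin stays an open hypothesis.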

How the results depend on the processing

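The tests with the first 1, 2 or 3 kb left out, a near part of 14 kb, shared bins, positions as deposited, 400 kb or beside over between at the terminus, χ sites more than 400 kb from dif and replichore-matched strands, the terminus list without uxaC, lists matched on distance and prophage genes far from dif were chosen after the results were seen. Of 142 alternative values of the 14 main results, 95 were the same within counting error or on the same side of the test, 38 moved, 9 were weaker, 0 were stronger and 0 were reversed. The mhpA-side near share difference, not called because its interval crosses 0, changed sign under 5 settings, counted as moved in 4 of them and as the same in 1. Of 255 values of 91 other results, 204 were the same, 39 moved and 12 reversed, among them the mhpA-side distance difference, whose interval excludes 0. The cause was not tested unless stated. Near shares had wider intervals on the mhpA side, where the excess was smaller, than on the lacY side.

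The lacY-side mean excess, 1.43, was 1.25 with whole totals, 1.40 with own flanks, 1.39 with the input as background, 1.51 with 5 kb bins, 2.59 with 50 kb windows and 1.52 with positions as deposited. The mhpA-side excess, 0.533, was 0.479, 0.558 and 1.04 with whole totals, own flanks and 50 kb windows. A 50 kb window raises both by construction. ChIP over input with whole totals was 1.06 and 0.49 (log2). The lacY-side near share difference, -17.2 points, was -20.0 with whole totals, -12.2 with own flanks, -13.3 with input, -14.4 with 5 kb bins, -13.9 with a 10 kb near part, -18.4 and -18.8 without the first 2 and 3 kb, and -15.0 with shared bins. The mhpA-side share difference, 2.09 with an interval across 0, was -16.5, -3.33, -3.77 and -4.25 with whole totals, own flanks, input and 50 kb windows, and under these 4 the mhpA-side distance difference, -3.05 kb, reversed to 9.01, 3.25, 2.72 and 1.19.

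Over the 6 array strains the ratio relation was weaker with own flanks, r 0.797 (exact p 0.0722), and with input as background without the first 1 or 2 kb, r 0.812 and 0.804 (exact p 0.0528 each). The lacY-side near share relation was weaker with own flanks, r 0.781 (exact p 0.0722), with input, r 0.811 (exact p 0.0583), with input and without the first 1, 2 or 3 kb, r 0.762, 0.727 and 0.731 (exact p 0.0833, 0.103 and 0.103), and with the natural χ strain added, r 0.385 (exact p 0.401). Leaving out each strain in turn gave r from 0.963 to 0.980 for the ratio (exact p 0.00833 to 0.025), 0.923 to 0.983 for the lacY-side share (0.00833 to 0.05) and 0.389 to 0.698 for the mhpA-side share (0.183 to 0.5). The chance per site, 0.87, was 0.81 with own flanks, 0.785 and 0.77 with near parts of 10 and 14 kb, 0.91 and 0.93 without the first 2 and 3 kb, and 0.705 to 0.88 with 1 strain left out.

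The terminus log2 ratio of the natural χ strain, 0.86, was 0.76, 0.62 and 0.54 with windows of 200, 50 and 400 kb, 0.90 with whole totals, 0.75 over input and 1.34 beside over between the χ sites. Libraries outside the central 95% at χ sites genome-wide, 2, were 0 with 10 kb flanks, 1 with sites more than 400 kb from dif, namely the natural χ strain in the opposite direction (percentile 2.00) and neither of those 2, 1 with matched strands (the strain with 5 sites), 3 with division by input (those with 4, 5 and 6 sites) and 2 with 2 kb flanks (2 sites, and the natural χ strain in the opposite direction); the strain with 5 sites reversed to -0.000356 with 2 kb flanks. The SOS median over input reversed to -0.0663 with whole totals, which lower every such ratio. The prophage median over input reversed to -0.0254 with the 9 genes more than 200 kb from dif. With positions as deposited rplM, rpsM, secG, lacZ and lacI reversed to 0.84, 0.14, 2.15, -0.0595 and 0.14, which the displacement of that file accounts for by construction.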

Other observations

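Apart from the settings with each strain's own flanks and with whole totals, which were chosen beforehand, the tests in this part were chosen after the results were seen.

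The ratio of origin to terminus signal differed between libraries. The median over 400 kb around the origin divided by that around dif was 2.10 in the ChIP library without the palindrome, 1.77 in the input and 1.48 in the natural χ strain. It was 1.35, 0.976, 1.69, 1.58, 1.64 and 1.40 in the strains with 1 to 6 χ sites. In the strain with 2 sites the terminus was thus as high as the origin, and that strain also had the highest single bin beside lacZ, 18.2 in lacA.

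The strain with 6 sites alone had a block of signal at 367500 to 368400, over the end of lacI and mhpR, with a mean relative signal of 6.53 against 0.939 to 1.34 in the other 8 libraries. The regulator gene mhpR was at 5.28 in that strain and 0.979 in the natural χ strain. Signal stepped near the outer end of lacA, at 361120, by 1.46, 1.80, 1.50 and 1.75 times in the strains with 1, 2, 4 and 6 sites, by 1.24 and 0.889 in those with 3 and 5, and by 1.15 in the natural χ strain. The mean over the first 2 kb of the lacY side divided by that from 2 to 5 kb was 1.42, 1.48 and 1.50 in the strains with 2, 4 and 6 sites and 0.982 to 1.08 in the other 4 palindrome ChIP libraries.

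The terminus signal was higher with the palindrome, and whether it needs the break at lacZ was tested in the library without the palindrome. There, signal beside the terminus χ sites over that between them, divided by input, had a log2 of 0.615 (0.56 to 0.67), above 97.8% of 45 other places but below the highest of them, 0.89 (SD 0.34). From this single library it stays open whether the step needs the lacZ break. Scaling by the median bin does not account for the difference, since with whole totals the log2 ratio was 0.896. The rise beside these χ sites without the palindrome was 26.0% of that in the natural χ strain. A lower yield of RecA-bound DNA in that library stays open and untested, because these files hold no place known to bind RecA independently of lacZ and the terminus.

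RecBCD travelling away from a break between the terminus χ sites could load RecA at χ. At 24 χ sites facing away from dif within 100 kb, signal on the outer side over the inner side lay at percentile 99.35 of random positions in the natural χ strain, with a median log2 of 0.14, and at 98.2 without the palindrome. The strains with 3 and 5 sites lay inside the central 95%, at 97.3 and 96.9, and the other 4 array strains at 99.1 to 99.4. At 12 sites of the other strand the natural χ median, again outer over inner side, was -0.16. Random sets for the 24 sites ran from -0.20 to 0.08 in that library, which includes this value. Taken as the side where RecA would be loaded over the other side, the 12 sites had 0.16, against 0.14 at the 24 sites. They are thus no control for the orientation of χ. The pattern was found on the same data, and sites within one rise are not independent of each other.

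The rise of the lacY-side near share with the number of χ sites may come in part from subtracting the background of another library, since with each strain's own flanks the exact p over 6 strains was 0.0722, with r still positive. The near share had r -0.338 (exact p 0.557) with the near excess, a measure of yield, and r -0.0500 (exact p 0.899) with the ribosomal RNA signal, a measure of background at highly transcribed genes. Over 6 single libraries these values exclude neither yield nor that background, and an effect of χ number stays open as well.

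At the next natural χ site on the lacY side, at 348150 in prpB, 13.5 kb from the start of the lacY side in the array strains and 14.9 kb in the natural χ strain, the log2 step in excess ran from -0.54 to 0.61 over the 6 array strains and was -0.97 in the natural χ strain. Its relation with the number of χ sites had r -0.570 (exact p 0.228) and rho -0.6 (exact p 0.242) over 6 strains. That leaves open whether RecBCD that passed the array recognised χ there.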
